A study of Mus musculus with 2 samples.

How the data were processed

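Primary neurospheres from the lateral ventricle walls of embryonic CD1 mouse forebrain, grown in LIF, were dissociated and captured by Drop-seq, per the labels' protocols. The libraries were sequenced on an Illumina instrument at a planned depth of 60000 reads per cell. The series text calls the assay single-nucleus sequencing, whereas the labels' protocols describe dissociated spheres and a single-cell library, and which of these holds was left open. The labels list 2 samples, both in the group of LIF-grown primary neurospheres. The deposited table holds whole-number UMI counts per gene and barcode, with 4000 barcodes of 12 bases in columns, no normalization and no column that assigns a barcode to a sample. The authors used genome build mm10, per the submitters' processing notes. The aligner, the counting program, the gene annotation and the rule that chose the barcodes are not given in the sources used here. Of the barcodes, 285 (7.125%) end in an unread base and 25 pairs differ by 1 base.

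Because nothing maps barcodes to samples, the table was analysed as 1 sample. Cells are not replicates, so no test, p-value or standard error was computed, and a count-model test planned for separable samples was not run. Sums of counts have exact Poisson intervals, shares of cells have exact binomial (Clopper-Pearson) intervals, and ratios of scaled counts (CPM) have exact conditional binomial intervals, all at 95% and for counting error only. Where a count was 0, the limit is that of 3 counts.

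Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Of the 4000 barcodes, 132 had too few genes and 148 too many mitochondrial UMIs, 235 were left out by either rule, and 3765 remained. Scrublet, run through scanpy 1.11.5 at an expected rate of 5%, called 0 doublets, which is taken as a caller that did not work, so no cells were removed as doublets. Genes in at least 5 cells were used for clustering. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, 30 principal components and 15 neighbours were computed, and Leiden clustering (leidenalg 0.10.2) was run at resolution 0.8 with seed 0. All genes of the readout and technical lists, mitochondrial genes and ribosomal protein genes were removed before the variable genes were chosen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

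There were 15 marker lists, 18 readout lists and 3 technical lists with 400 genes in all, of which 357 were in the table, and they were fixed before the data were examined, as were the filters, the settings and the rule for named genes. That rule allows any gene of the lists, summarised by how many members with at least 50 UMIs had a ratio of the cluster to all other cells with its whole interval above 1.5 or below the inverse of 1.5, and the 10 leading genes of a cluster among genes with at least 100 UMIs. The markers were fixed beforehand, but the rule for naming a cluster was tightened after the clusters were seen. A cluster was named only if at least 3 markers of a list, and most of its measured markers, lay above that threshold and the list had more genes among the 10 leading genes than any other list. Leading genes that were also clustering genes helped to define a cluster and are not results. Gene positions are those of GENCODE release M21 on the same build, which held 17959 of the 19144 symbols (93.8%). Genes with near-identical copies can share reads, and their counts are uncertain.

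To compare cells at equal depth, each cell was thinned at random to 1000 UMIs and shallower cells were left out. A cell was called cycling with 2 or more UMIs of the 93 S and G2/M genes. The call by 6 proliferation genes was added after the data were seen.

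The ratio threshold was tested on simulated counts with the totals of clusters 8 and 9 against the other cells, over 9871 genes with 50 changed at each simulated fold. In the cluster 8 simulation, 90.0% of 4-fold and 34.0% of 2-fold rises passed, 44.0% of 4-fold and 20.0% of 2-fold falls passed, and 0.0414% of unchanged genes passed. In the cluster 9 simulation the shares were 76.0% and 18.0% for rises, 16.0% and 4.00% for falls, and 0.165% for unchanged genes. These counts were drawn as sums with counting error only, without variation between cells and without clustering. The shares of unchanged genes therefore do not give the rate of false passes among the real clusters. The clustering was tested on 3765 simulated cells with the real depths. Cells drawn from the 9 cluster profiles gave 9 clusters with an adjusted Rand index of 0.771, and 100% of simulated cluster 9 cells, 98.1% of cluster 8 cells and 57.1% of cluster 1 cells fell in a single cluster. Cells drawn from 1 profile were split into 4 clusters.

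Alternatives planned beforehand were gene minimums of 200 and 1000, mitochondrial limits of 5% and none, doublet calls kept, Leiden resolutions of 0.4 and 1.2, readout genes allowed among the clustering genes, 15 principal components, seed 1, thinning to 500 or 2000 UMIs or not at all, a cycling call at 4 UMIs, CPM totals without mitochondrial and ribosomal protein genes, no minimum of UMIs, and means of per-cell CPM. Added later were settings without barcodes ending in an unread base, without cells under 2000 UMIs, without the 5% of cells with the highest Scrublet scores, and without cluster 7. Transcripts were aligned to each other with blastn 2.17.0 to find near-identical copies.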

Results

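Transcripts were measured by Drop-seq, a droplet method that tags the polyadenylated RNA of each captured cell or nucleus with a barcode and each molecule with a unique molecular identifier (UMI). The sources name both nuclei and dissociated cells, and barcodes that passed the filters are called cells throughout. The material came from primary neurospheres, floating colonies grown from the walls of the lateral ventricles of embryonic CD1 mouse forebrain. The culture medium held leukemia inhibitory factor (LIF) at 10 ng/mL, the cytokine used to grow primitive neural stem cells; the protocol also names an additive EFH without saying what it is or which cells received it. By the protocol, colonies of at least 50 μm counted as primitive neurospheres. The labels list 2 samples in a single group, and a single count table held 4000 barcode columns with nothing to assign them to a sample, so the table was treated as 1 sample. Whether it holds both samples could not be told from the sources. No treatment was contrasted, no replicate spread could be computed and no test was run. All intervals are 95% intervals that cover counting error only.

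The table held 17591915 UMIs over 19144 genes, with a median of 3681.5 UMIs and 1920.5 genes per barcode. After filtering, 3765 cells with 17395968 UMIs were kept, at a median of 3869 UMIs (range 638 to 54060) and 1993 genes. Mitochondrial genes took 3.03% of their UMIs, ribosomal protein genes 8.63% and the nuclear RNA Malat1 0.321%.

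The series title describes the stem cells as GFAP-negative, so the first question was how much Gfap, the astrocyte and adult neural stem cell intermediate filament, these colonies held. Gfap (chromosome 11, 102887336 to 102900912, mm10) was at the edge of detection. It had 10 UMIs in 10 of the 3765 cells, a share of 0.266% (exact binomial interval 0.127 to 0.488) and a level of 0.575 CPM, the count scaled to a common total (exact Poisson interval 0.276 to 1.06). The 10 cells lay in clusters 1 (2 cells), 2 (3 cells), 3 (1 cell), 5 (1 cell), 6 (1 cell) and 8 (2 cells). None of the 31 neuron-like cells, which should lack the transcript, had a Gfap UMI, but at their median of 1825 UMIs that allows a share of up to 9.68%, so a background share could not be set. Over all 3765 cells other filaments of radial glia were abundant. Vim, encoding vimentin, reached 3522 CPM, and Nes, encoding nestin, reached 756 CPM.

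Neural progenitor transcripts dominated the fixed marker lists. All 16 radial glia or neural stem cell markers had at least 50 UMIs, together 19598 CPM (19532 to 19664). Fabp7, the brain lipid-binding protein of radial glia, was at 7166 CPM and ranked 3 among all genes. The transcription factor genes Sox2 and Sox9 were at 433.0 and 247 CPM, and the glutamate transporter gene Slc1a3 at 582 CPM. Olig1 and Olig2, transcription factors of ventral progenitors and the oligodendrocyte lineage, were at 1267 and 622 CPM, while the committed oligodendrocyte precursor genes Pdgfra and Sox10 were at 2.64 and 2.53 CPM. Other genes of the precursor list ranged from Neu4 and Gpr17, at 0.115 and 0.632 CPM, to Cspg4, Bcas1 and Cspg5, at 27.4, 35.4 and 62.5 CPM. The oligodendrocyte precursor list as a whole was at 2021 CPM and the astrocyte list at 2050 CPM. Most of the latter came from Cst3, Aldoc and Apoe, and the mature astrocyte water channel gene Aqp4 was at 2.30 CPM. Intermediate progenitor markers were at 719 CPM.

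Transcripts of other lineages were scarce. The microglia or macrophage list had 20 UMIs (1.15 CPM), the fibroblast or meningeal list 37 UMIs (2.13 CPM) and the endothelial list 192 UMIs. The mural, ependymal and choroid plexus lists were at 15.6, 28.2 and 32.8 CPM. None of the 6 erythroid genes was in the table. The oligodendrocyte list was at 98.2 CPM, of which Cnp supplied 86.1 CPM. The immature neuron list was at 1007 CPM, largely from Gap43 and Map2, which progenitors also carry. The inhibitory neuron lineage list was at 32.7 CPM and the excitatory list at 12.4 CPM. Among regional genes, the dorsal forebrain list was at 116 CPM, mainly Emx2, Lhx2 and Pax6. Of the 10 ventral forebrain genes, 5 had at least 50 UMIs. The 9 posterior HOX genes, which mark hindbrain and spinal cord, had 6 UMIs in all, or 0.345 CPM.

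**Figure D1:**
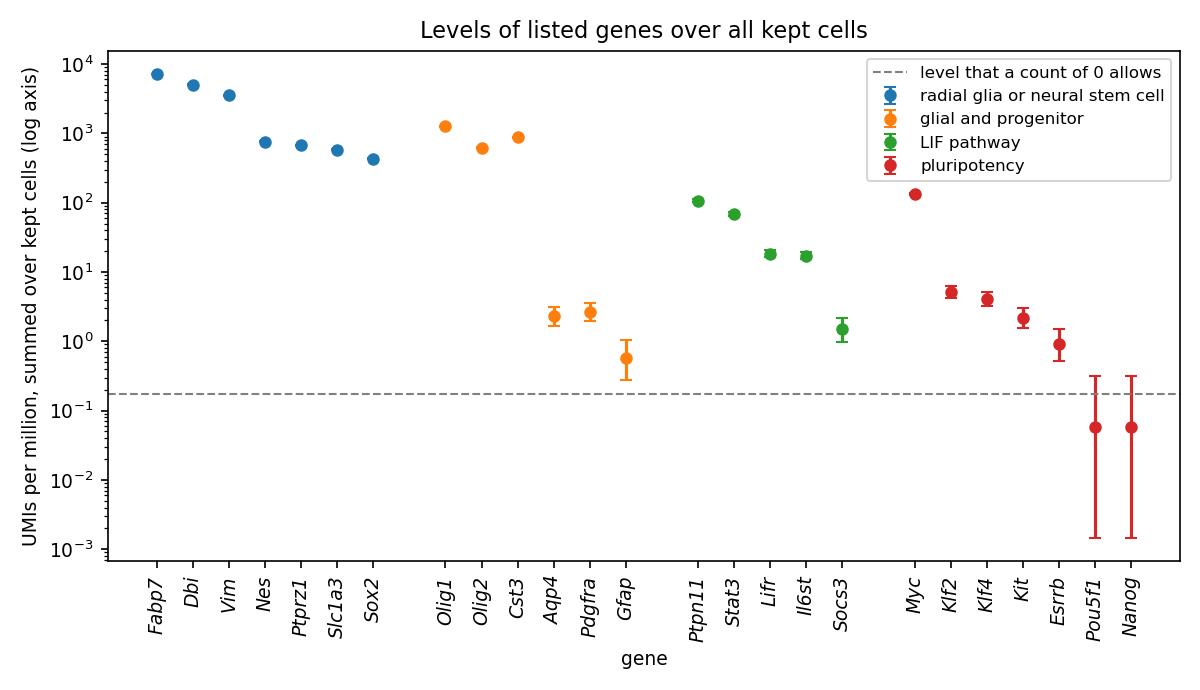
Level of listed genes in CPM, from UMIs summed over the 3765 kept cells, on a log axis. Points are levels, bars are exact 95% Poisson intervals for counting error, and the dashed line is the 0.172 CPM that a count of 0 allows; Gfap lies at 0.575 CPM and Fabp7 at 7166 CPM.

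Primitive neural stem cells are known in the field for low Oct4 expression, so pluripotency genes were examined next. Pou5f1, encoding Oct4 (chromosome 17, 35506018 to 35510772), had 1 UMI over all kept cells, or 0.0575 CPM (0.00146 to 0.320). Nanog also had 1 UMI and Esrrb had 16, while the receptor gene Kit had 38 (2.18 CPM). Of the 20 genes on the list, at 158 CPM in all, 14 were in the table and 6 reached 50 UMIs. Those were Myc at 133 CPM and Klf2, Erbb2, Klf5, Klf4 and Mycn at 2.87 to 5.17 CPM, all of which are also expressed outside pluripotent cells. Hoxb3, a posterior HOX gene, also had 1 UMI, and Pou5f1 expression was not detectable at this depth.

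The machinery that receives LIF was transcribed. Of the 13 genes of the LIF receptor and STAT3 list, at 338 CPM in all, 9 had at least 50 UMIs, and none of these 9 lay beyond the fold threshold used for clusters in any of the 9 clusters. Clusters 7 and 9 held only 189804 and 82165 UMIs, so few counts of the lower genes fell there and differences could be missed. Lifr, the LIF receptor, was at 18.3 CPM (16.4 to 20.5) and its partner Il6st, gp130, at 17.1 CPM. Stat3 was at 68.4 CPM. The STAT3 target Socs3 had 26 UMIs, or 1.49 CPM (0.976 to 2.19). Among growth factor receptors, at 259 CPM in all, Egfr was at 144 CPM and Fgfr1 at 74.0 CPM. BMP target genes were at 720 CPM, chiefly Id3, and Notch pathway genes at 490 CPM, chiefly Hes1. All 10 p53 targets were measured, at 2364 CPM. Cdkn1a, the cell cycle inhibitor p21, was at 931 CPM, and Bax and Ccng1 were at 631 and 358 CPM. Sterol synthesis genes stood at 2028 CPM, immediate early and dissociation stress genes at 1399 CPM and interferon response genes at 676 CPM, the last from B2m, H2-K1, Ifitm3 and other constitutive members, since Ifit1, Ifit3, Isg15, Irf7 and Oasl2 had 7 UMIs or fewer each. Genes of quiescent neural stem cells were at 1630 CPM, hypoxia and glycolysis genes at 2389 CPM, and unfolded protein and amino acid response genes at 1373 CPM. Gapdh, at 13.9 CPM, and Pgk1 have many near-identical copies in the genome and their levels are uncertain.

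The cells fell into 9 clusters when every readout gene was held out of the clustering genes. Genes outside the lists that vary together with them could remain among the clustering genes. The counts of genes per list and cluster are therefore not independent of how the clusters were made. The radial glia list stayed within ratios of 0.711 to 1.23 to the other cells in all but the smallest cluster, and 8 clusters carry a number only. Clusters 1 to 4 held 23.9% (22.5 to 25.2), 21.5% (20.2 to 22.9), 18.4% (17.2 to 19.7) and 16.8% (15.7 to 18.1) of the cells. Clusters 5 to 8 held 8.58% (7.70 to 9.52), 3.67% (3.09 to 4.32), 3.45% (2.89 to 4.09) and 2.82% (2.31 to 3.40). Cluster 9 was neuron-like, with 31 cells or 0.823% (0.560 to 1.17). Clusters 1 and 7 were shallow, at medians of 2097.5 and 1011 UMIs, and the same procedure split simulated cells of a single profile into 4 clusters whose median depths differed by up to 3.92 times, so a boundary that follows depth need not separate kinds of cells. The highest ratio in cluster 1 among the genes eligible as leading genes was 2.001 (Mir5136), and of the readout genes there Cenpa was above the fold threshold, while 10 of 52 G2 and M phase genes and Bnip3 were below it.

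The clusters differed in cell cycle genes, whose lists stood at 4108 CPM for S phase and 9779 CPM for G2 and M phase over all kept cells. Cluster 3 had 41 of 41 S phase genes above the fold threshold, meaning a ratio to the other cells with its whole interval above 1.5. Ccne2, the cyclin of S phase entry, was 5.76 times higher (5.10 to 6.51) and the replication licensing gene Cdc6 4.76 times higher (3.96 to 5.73). Cluster 4 had 48 of 52 G2 and M phase genes above it. The mitotic ubiquitin-conjugating enzyme gene Ube2c was 9.21 times (8.69 to 9.76) and the spindle kinase gene Aurka 9.09 times (7.86 to 10.5) higher. Cluster 2 was the reverse of both, with 37 of 41 S phase and 48 of 52 G2 and M phase genes below it. There the replication inhibitor gene Gmnn had a ratio of 0.188 (0.157 to 0.224) and the spindle gene Nusap1 0.0558 (0.0426 to 0.0719). Cell cycle genes outside the lists remained among the clustering genes, so phase did shape these clusters.

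At equal depth of 1000 UMIs, S and G2/M list genes supplied 24.5 of 1000 UMIs in cluster 4 and 15.9 in cluster 3, against 5.20 in cluster 2, 5.76 in cluster 5, 5.06 in cluster 6 and 4.46 in the neuron-like cells. Over all 3576 cells of that depth the value was 12.6, and 189 shallower cells were left out, 104 of them in cluster 1 and 65 in cluster 7. The planned call of a cycling cell, 2 or more such UMIs, took in 95.7% of cells (94.98 to 96.3) and 89.3% of neuron-like cells (71.8 to 97.7), which should not divide, so it did not separate cycling from resting cells. Without thinning it took in 99.6% and 96.8%. A narrower call was chosen after these values were seen, a UMI of any of the 6 proliferation genes Mki67, Top2a, Cdk1, Rrm2, Pcna and Ube2c. It took in 60.4% of cells (58.8 to 62.0). Its share was 95.1% (93.1 to 96.7) in cluster 4, 86.4% (83.7 to 88.9) in cluster 3, 64.0% (60.5 to 67.3) in cluster 1 and 73.8% (61.5 to 84.0) in cluster 7. It was 30.02% (26.9 to 33.3) in cluster 2, 28.5% (23.6 to 33.8) in cluster 5, 22.5% (15.8 to 30.3) in cluster 6 and 33.3% (24.3 to 43.4) in cluster 8. The neuron-like cells had 17.9% (6.06 to 36.9), which serves as the background of this call.

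**Figure D2:**
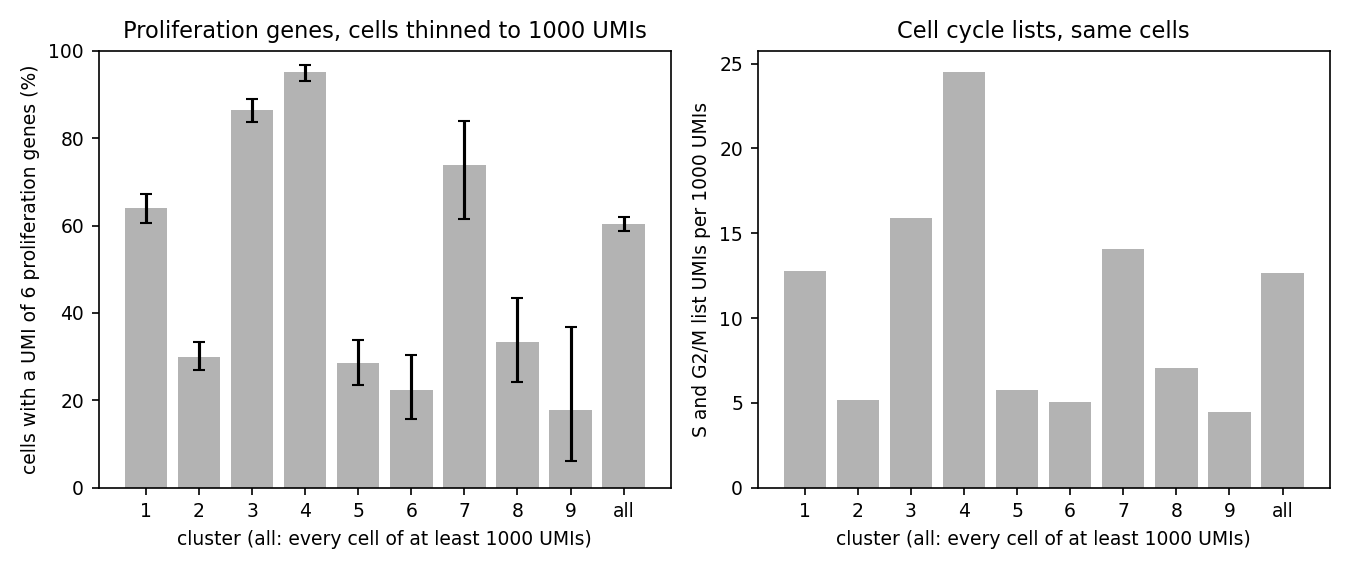
Left, percent of cells with a UMI of 6 proliferation genes after thinning to 1000 UMIs, by cluster, with exact 95% binomial intervals; right, UMIs of the S and G2/M lists per 1000 UMIs in the same cells. Clusters 3 and 4 stand highest, at 86.4% and 95.1%, and clusters 2, 5, 6, 8 and 9 lie at 33.3% or lower.

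Cluster 2, with low cell cycle lists, differed little from the rest in p53 genes and receptors of LIF. None of its 10 p53 targets, 6 pluripotency genes or 9 LIF pathway genes lay beyond the fold threshold. Cdkn1a had a ratio of 1.201 (1.16 to 1.24) and Trp53inp1 1.66 (1.48 to 1.86). Hes5, Cdkn1b and Cdkn1c lay below the threshold, with ratios of 0.437, 0.581 and 0.233. Of its leading genes that were not clustering genes, Klhl36 had the highest ratio, 2.99 (2.16 to 4.15).

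Cluster 5 combined low cycling with Delta ligands. Dll3 was 5.64 times (4.70 to 6.73) and Dll1 4.04 times (3.22 to 5.04) higher than in the other cells; both encode Notch ligands of cells about to differentiate, and they were the 2 of 10 Notch pathway genes above the threshold. Over the alternatives that kept such a cluster, the ratio ranged from 4.597 to 19.4 for Dll3 and from 3.01 to 6.78 for Dll1. In this cluster 47 of 52 G2 and M phase genes and 18 of 41 S phase genes were below it. Cdkn1c, the inhibitor p57, was 3.63 times higher (2.79 to 4.66) and Sox9 2.03 times (1.85 to 2.23). Olig1, Bcas1 and Cnp, genes of the oligodendrocyte lineage, were higher by 2.19, 3.06 and 3.70 times, but they were among the clustering genes. Of 9 measured intermediate progenitor markers 4 were above the threshold, Dll1, Dll3, Btg2 and Mfng, with a list ratio of 1.93 (1.82 to 2.04). That list alone had a gene, Dll3, among the 10 leading genes. Of 12 astrocyte markers 3 were above it and 1 below, and Neurod1 of the excitatory list was above it. No lineage name was given, since 4 of 9 is not most of the list. The S phase count was not stable, falling to 0 under 4 of the alternative settings, where the matching cluster was smaller, at 2.66% to 3.45% of cells, and 28 rather than 47 G2 and M phase genes were below the threshold when readout genes were allowed in the clustering.

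Cluster 6 had raised genes of the amino acid starvation and unfolded protein response. Of 10 genes on that list, 6 were above the threshold and 0 below. The glutathione-degrading enzyme gene Chac1 was 14.6 times higher (10.9 to 19.4), Trib3 12.5 times (7.41 to 20.3), Ddit3 (CHOP) 6.16 times (4.72 to 7.94), the asparagine synthetase gene Asns 4.46 times (3.88 to 5.10) and Atf4 2.74 times (2.46 to 3.05). Hspa5, the endoplasmic reticulum chaperone BiP, had a ratio of 0.791 (0.699 to 0.891), so the rise did not extend to it. In this cluster 47 of 52 G2 and M phase genes were below the threshold. Leiden clustering at resolution 0.4 and the lower gene minimum did not separate these cells.

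Cluster 8 had raised hypoxia and glycolysis genes. Of 13 measured hypoxia and glycolysis genes, 12 were above the threshold, the exception being Pgk1, at 2.35 (1.38 to 3.77). The mitophagy receptor gene Bnip3 was 33.0 times higher (28.3 to 38.3), Ankrd37 24.8 times (19.9 to 30.8), the pyruvate dehydrogenase kinase gene Pdk1 12.9 times (10.1 to 16.3), Vegfa 12.7 times (11.02 to 14.5) and the glucose transporter gene Slc2a1 10.2 times (7.80 to 13.3). Of 10 Notch pathway genes 3 were above it, the target genes Hes5, Hey1 and Hes1, by 5.36 (4.40 to 6.48), 2.86 (1.75 to 4.45) and 2.32 (1.99 to 2.69) times. Of 11 quiescence genes 5 were above it, with Cdkn1c 26.1 times higher (21.2 to 32.1). Over the alternatives that kept such a cluster, the Cdkn1c ratio ranged from 16.7 to 36.1. Astrocyte markers had 10 of 12 members above it, but most of these, Apoe and Aldoc among them, were clustering genes and none was among the 10 leading genes, so the cluster was not named. Of those held out or not selected, Slc1a2 was 2.61 times (1.73 to 3.797), Slc4a4 2.35 times (1.81 to 3.002) and Mlc1 2.11 times (1.64 to 2.69) higher. Egfl7 and Tagln, from the endothelial and mural lists, and Otx2, from the choroid plexus list, were above it as well. Under 3 alternatives, a change of seed among them, most of these cells joined cells of cluster 5 in a single cluster. Without cells under 2000 UMIs, 78 of 87 fell with 15 neuron-like cells in a cluster of 245, most of which came from other clusters.

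The neuron-like cluster 9 was named from the immature neuron list, 11 of whose 12 measured genes were above the threshold, 4 of them among its 10 leading genes. These 4 and most of the others were clustering genes, which helped to define the cluster. Rbfox3 and Elavl4, which were not, were 16.2 times (6.34 to 34.8) and 5.14 times (1.65 to 12.2) higher, from 7 and 5 UMIs. The regional genes were held out of the clustering. Of the 5 measured ventral forebrain genes, Dlx1 was 39.0 times (17.7 to 77.4), Dlx2 13.5 times (5.70 to 27.4) and Nkx2-1 15.3 times (4.03 to 41.5) higher, from 10, 8 and 4 UMIs. Gad1 and Gad2, which make the inhibitory transmitter GABA, were higher too but were clustering genes, as was Neurod1, the single measured gene of the excitatory list, at 17.9 times (9.56 to 30.9). Cdkn1a had a ratio of 0.300 (0.190 to 0.450) and Ccng1 0.305 (0.139 to 0.580), the 2 of 10 p53 targets below the threshold. The cluster had 82165 UMIs in all, and a simulated 2-fold rise passed the threshold in 18.0% of genes at that depth, so smaller differences could be missed. The 31 cells stayed together under every alternative that kept them all, but joined another cluster when 1000 genes were required, when at most 5% mitochondrial UMIs were allowed, and when cells under 2000 UMIs were left out.

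**Figure D3:**
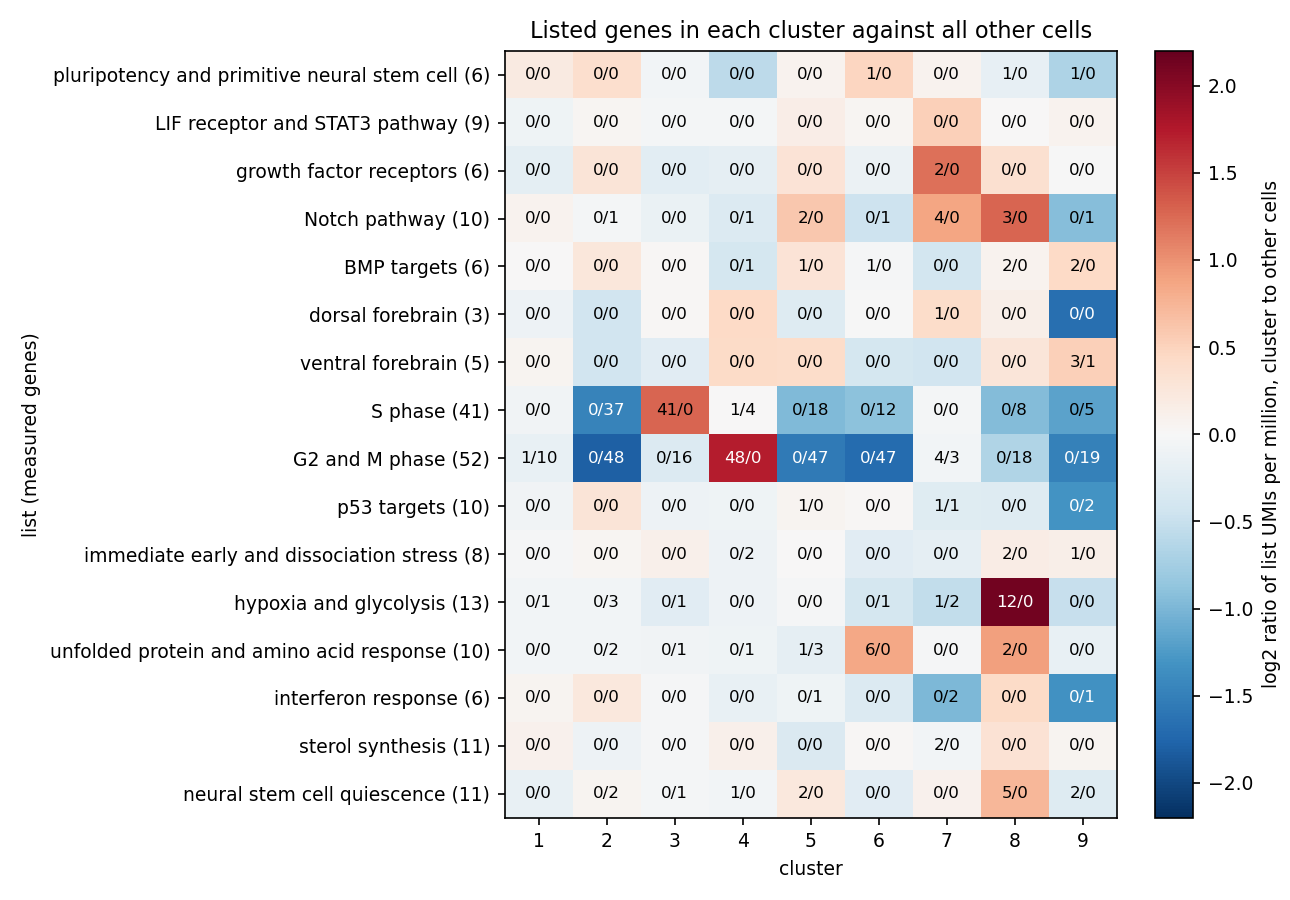
Log2 ratio of the summed CPM of each fixed list in a cluster to that in all other cells, by color. Each cell of the grid gives the number of genes above and below the 1.5-fold threshold, such as 41 and 0 for S phase genes in cluster 3 and 12 and 0 for hypoxia and glycolysis genes in cluster 8, and the measured genes of each list are in parentheses.

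Cluster 7 was set apart by RNA make-up. Malat1 took 3.54% of its UMIs against 0.286% in the other cells, ribosomal protein genes took 4.85% against 8.68% and mitochondrial genes 4.79% against 3.01%. Xist, the RNA of the inactive X chromosome, was at 3182 CPM against 517 CPM. Notch1, Notch3, Jag1 and Dll1 were above the threshold, 4 of 10 Notch pathway genes, as were Fgfr1 and Fgfr3. At a 5% mitochondrial limit 1 Notch pathway gene, not 4, was above it. Of 52 G2 and M phase genes, 4 were above it and 3 below. In the 235 barcodes removed by the filters, nuclear-retained RNAs were 10.6 times higher than in kept cells. The Notch pathway and growth factor receptor lists were higher there too, by 1.72 and 3.17 times. The rises in cluster 7 therefore cannot be told apart from its RNA make-up.

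Cells with and without a Gfap UMI were to be compared at equal depth, but only 1 cell kept a Gfap UMI after thinning to 1000 UMIs. Its 1 astrocyte list UMI gave a ratio of 0.470 (0.0119 to 2.62), which excludes little. Without thinning, the 10 cells with a Gfap UMI, at a median of 4106.5 UMIs against 3868, had the astrocyte list 1.84 times higher (1.56 to 2.15) and the radial glia list 1.23 times higher (1.16 to 1.31), with ratios of 1.04 (0.830 to 1.28) for the oligodendrocyte precursor list and 0.938 (0.623 to 1.36) for the intermediate progenitor list. Of their 156 astrocyte list UMIs, 81 came from the 2 cells in cluster 8, where that list, summed over the cluster, was 3.93 times higher than in the other cells. In a split made after these values were seen, the astrocyte ratio was 1.29 (1.01 to 1.62) for the 8 cells of the other clusters and 0.948 (0.751 to 1.18) for the 2 within cluster 8.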

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

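All tests in this part were chosen after the results they concern were seen, and the Xist and Y-linked counts used for doublets had been looked at by cluster. Apart from the comparison with cluster 7, the report did not use the 235 barcodes removed by the filters, which held 195947 UMIs at a median of 671 per barcode. Of the marker and readout lists, 2 stood at more than 1.5 times their level in kept cells by the whole interval. The inhibitory neuron lineage list was at 163 CPM against 32.7 CPM, a ratio of 5.002 (3.39 to 7.14) and above the 15.3 CPM that a count of 0 allows. The growth factor receptor list was at 822 CPM against 259 CPM, a ratio of 3.17 (2.70 to 3.72). Nuclear-retained RNAs stood at 34494 CPM in these barcodes against 3247 CPM, Xist at 2516 CPM against 546 CPM, and Y-linked genes at 204 CPM against 70.6 CPM.

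In the neuron-like cluster of 31 cells, the first pattern weighed, doublets of a neuron and a progenitor would keep the radial glia list at a ratio of 0.5 or more, and it was at 0.367 (0.338 to 0.397). That ratio is for the 31 cells summed, so it speaks only against a cluster made up wholly of such doublets. The radial glia list still stood at 7205 CPM there. A mixture of doublets and neurons, in shares that these values do not set, is not excluded. Free neuronal RNA spread over droplets would give all cells a like level of neuronal genes. The inhibitory neuron lineage genes that were not clustering genes had a summed ratio of 16.2 (10.2 to 24.6). Most of that sum came from Dlx1 and Dlx2, with 10 and 8 UMIs in the cluster, whose ratios are given above. The cluster was found through other neuronal genes, so this is not an independent test. Whether the mitochondrial limit lowers the share of neurons stays open, since without it the cluster held 35 cells, or 0.905% (0.631 to 1.26) against 0.823% (0.560 to 1.17), while the 148 barcodes above it had the inhibitory neuron lineage list 4.33 times higher than kept cells (2.66 to 6.69), from 21 UMIs, with 5 barcodes holding 2 or more. Snap25, Celf4, Myt1l, Elavl3 and Map2 were also higher there, by 1.57 to 27.0 times, and Gap43, which progenitors carry too, was lower, at 0.563 (0.405 to 0.761), but Malat1 was 8.76 times higher, so a general rise of nuclear RNA is not excluded. Whether these neurons arose in culture or were carried over from the embryo was not tested, and no biological explanation was.

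The second pattern is cluster 8, with its hypoxia, glycolysis and astrocyte genes. Loss of RNA from damaged cells would raise the mitochondrial share, and its median was 2.23% against 2.96% in all kept cells. It would also raise nuclear-retained RNAs, and these were 1.52 times higher (1.45 to 1.59). These signs went opposite ways, so damage is not excluded. Stress during dissociation stays open: the immediate early and stress list had a ratio of 1.12 (1.03 to 1.21), but its members went both ways, with Ier3 at 5.24 (4.23 to 6.44) and Fos at 2.76 (1.87 to 3.95) against Hsp90aa1 at 0.681 and Dnaja1 at 0.6703. Doublets also remain open, because 5 of 106 cells had both Xist and Y-linked UMIs against 81 of 3659 others, a ratio of 2.13 (0.674 to 5.18) whose interval is too wide to decide. A position in the oxygen-poor core of large colonies is a hypothesis that these data did not test.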

How the results depend on the processing

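The alternatives without barcodes ending in an unread base, without cells under 2000 UMIs, without the highest Scrublet scores and without cluster 7 were chosen after seeing the data. Over all alternatives run, 289 values of the counts of genes per list and cluster, the Gfap results and the neuron-like and whole-culture shares stayed within their interval, or within 1.5 times for counts of genes, and 19 did not. Of the other values, 456 stayed, a gene's ratio counting as such when it kept its side of the threshold whatever its size, and 75 moved, all shares of clusters 1 to 8 or of their cycling cells. These tallies overstate stability. They count the setting with doublet calls kept, which could change no value. They also count gene ratios with no minimum of UMIs, which that setting could not change. Pairs of a result and an alternative that gave no value are left out. The Gfap share ranged from 0.258% to 0.327% and the neuron-like share, where the cluster separated, from 0.811% to 0.905%. S phase genes above the threshold in cluster 3 ranged from 39 to 41, G2 and M phase genes in cluster 4 stayed at 48, and hypoxia and glycolysis genes in cluster 8 at 12 to 13.

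The cycling share moved with its own construction, since fewer UMIs per cell leave fewer cells with 2 of them. Over all cells it was 84.3% at 500 UMIs, 99.7% at 2000 UMIs, 99.6% unthinned and 83.5% at 4 UMIs, against 95.7%, and in the neuron-like cells 61.3% at 500 UMIs and 53.6% at 4 UMIs against 89.3%. Without thinning 10 cells, not 1, had a Gfap UMI. The astrocyte list ratio of Gfap cells was 2.88 at a 5% mitochondrial limit against 0.470, which rested on 1 cell. In cluster 5, the S phase genes below the threshold numbered 0 at a 5% mitochondrial limit, with readout genes allowed in the clustering, without barcodes ending in an unread base and without the highest Scrublet scores, 8 at resolution 1.2, 5 with seed 1 and 10 without cells under 2000 UMIs, against 18; with readout genes allowed, 28 G2 and M phase genes were below it against 47. Where that number was 0, the matching cluster held 2.66% to 3.45% of cells against 8.58%, so it describes fewer cells; with readout genes allowed, 205 of the 323 cells joined 600 of cluster 2, and without barcodes ending in an unread base 162 of 304 joined 673. Notch pathway genes above it in cluster 7 fell from 4 to 1 at a 5% limit. With means of per-cell CPM, 30 G2 and M phase genes and 4 p53 targets were below it in the neuron-like cells, against 19 and 2. For clusters 5 and 7, the Gfap cells and the means, the cause was not tested.

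Some alternatives gave no value. Cluster 8 was merged with cluster 5 cells with seed 1 (105 of its 106 cells in a cluster of 263), with no mitochondrial limit and at 1000 genes. The neuron-like cells joined that cluster at 1000 genes and joined cluster 6 cells at a 5% mitochondrial limit. Without cells under 2000 UMIs they lay with cluster 8 cells in a cluster of 245, made up mostly of cells of other clusters. Clusters 5 and 6 were not separate at 200 genes or at resolution 0.4, nor cluster 7 at 1000 genes, at resolution 0.4 or without cells under 2000 UMIs. Keeping doublet calls changed nothing because there were none. The agreement of the 2 samples, leaving out a replicate and DESeq2 were not run because no column tells the samples apart. No paired analysis was possible because the barcodes carry no replicate number.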

Other observations

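The tests of cluster make-up, of copies of Rpl26 and of Rps19 were set before their results were seen; the others in this part, and the genes named, were chosen after. Some cells could be assigned a sex by Xist, the RNA of the inactive X chromosome, and by 4 Y-linked genes. At least 2 Xist UMIs and no Y-linked UMI were found in 1689 cells (median 4491 UMIs), a Y-linked UMI and no Xist UMI in 556 cells (median 4582), and at least 2 Xist UMIs with a Y-linked UMI in 86 cells, or 2.28% of kept cells. The others were not assigned, 930 with neither and 504 with 1 Xist UMI. In the deeper cells, split at the median depth, 3.51% had both, where independence would give 14.2%.

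Rpl26 (chromosome 11, 68901583 to 68906989), an autosomal ribosomal protein gene, was at 58.5 CPM in cells with Y-linked UMIs and 354 CPM in cells with Xist, a ratio of 0.165 (0.141 to 0.193). A different make-up of clusters is argued against, since the highest ratio within clusters 1 to 4 was 0.178 (0.102 to 0.291); cluster 8, from 4 and 37 UMIs, had 0.713 (0.185 to 1.98), too wide to place. A general difference in ribosomal protein genes is also argued against by the median ratio of 0.982 over 93 other Rpl and Rps genes. Reads divided with near-identical copies stay open: 10 annotated genes, Rpl26 included, matched over 100 bases at 90% identity, but Rpl26 alone of these was in the table, so the planned sum over copies was that of Rpl26 itself and tested nothing.

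Rpl26 was unevenly spread among the Xist cells. No Rpl26 UMI was found in 55.5% of them, where counts scattered at random around their mean would leave 24.2%, while in Y-linked cells 74.8% had none against 74.3% at random. Among Xist cells of at least the median depth, 292 had 3 or more Rpl26 UMIs (median 6814.5 UMIs) and 466 had none (median 5603). Cluster 2 held 25.3% and 27.0% of them, cluster 3 33.2% and 27.7%, cluster 4 24.3% and 27.0%, cluster 6 5.14% and 2.36%, and cluster 8 1.03% and 3.22%. Of 4729 genes compared between them, 25 lay beyond the fold threshold, Rpl26 included, on 16 chromosomes with the mitochondrial genome counted among them. Of these, Cwc22 was 3.91 times higher (3.17 to 4.87) in the Rpl26 cells, Rpl35a 3.09 times (2.76 to 3.46) and the ribosomal RNA gene mt-Rnr1 of the maternally inherited mitochondrial genome 1.85 times (1.77 to 1.94), while Rab3b had a ratio of 0.270 (0.233 to 0.312), Ly6e 0.314 (0.239 to 0.408) and Atp5g1 0.345 (0.304 to 0.391). With clusters as strata these ratios were 3.75, 3.07, 1.80, 0.272, 0.315 and 0.343.

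CD1 mice are outbred, and a mixture of a few source embryos that differ in genotype is a candidate explanation for these sets of cells. It was tested with Rps19, which was 1.75 times higher (1.70 to 1.79) in Y-linked cells than in Xist cells and was predicted to be lower in the Xist cells with Rpl26. Its ratio there was 1.01 (0.968 to 1.05), which goes against a mixture in which Rpl26 and Rps19 vary together. Of the autosomal genes that also lay beyond the fold threshold between Y-linked and Xist cells, Gm8420 and Thy1 went the way of Rpl26. They were lower in Y-linked cells, with ratios of 0.483 and 0.366, and higher in the Xist cells with Rpl26, with ratios of 3.799 and 2.27. By contrast, 1700025G04Rik was lower in Y-linked cells, at 0.531, and also in the Xist cells with Rpl26, at 0.6305. A mixture of more embryos, with Rps19 shared by both sets of Xist cells, stays open. So do a difference between the 2 samples, if both are in the table, and a difference between single colonies. For 1 pair of genes, part of the pattern may lie in how reads were counted. Rps3a1 (chromosome 3, 86137940 to 86142702) was 1.85 times higher in the Rpl26 cells. Its processed pseudogene Rps3a3 (chromosome 13, 108670603 to 108671397), 98.9% identical over 795 bases, had a ratio of 0.356. Their summed ratio was 0.849 (0.814 to 0.885), so the sum was still lower in the Rpl26 cells by its whole interval. Reads of the same transcript may have gone to either row. Why they would divide differently between cells of the same table was not tested, so a difference in source is not excluded.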
